A study of Rattus norvegicus with 12 samples.

How the data were processed

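Liver RNA of 12 rats was measured on Affymetrix arrays, 1 array per animal. Per the labels, the groups were 3 germ-free Sprague-Dawley rats (animals 1, 3 and 4), 3 conventional Sprague-Dawley rats (6, 7 and 8), 3 untreated Han Wistar rats (1, 2 and 3) and 3 antibiotic-treated Han Wistar rats (13, 14 and 15). The labels' protocols name streptomycin at 4 mg/ml, penicillin at 2 mg/ml and a 10X stock, of which 30 mL was made up with 270 mL of drinking water to 300 mL. They do not settle whether the concentrations are those of the stock or of the drinking water. Animals had free access to it for 8 days. RNA was extracted with Qiagen RNeasy columns, and 5 ug of total RNA was labelled with biotin, per the labels' protocols.

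The deposited table holds 1 linear signal intensity per probe set and array for 31099 probe sets, without detection calls. The submitters' processing notes name MAS5, and its version is not given in the sources used here. The trimmed mean of every array (2% removed at each end) lay at 100.0, so the values were used as deposited with no further scaling, by a rule that allowed differences of up to 1.1-fold. After 57 control probe sets were set aside, 31042 remained, of which 20826 had 1 gene symbol in the platform annotation, 436 several and 9780 none. Symbols were updated to the GRCr8 gene table through the gene identifier (20764) or accession (2), and 66 were kept as given. Coordinates are not printed because no build goes with the array values.

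Probe sets with a mean signal at or above the median of 19.67 were kept (15523). One probe set, that with the highest mean signal, stood for each gene, which gave 9300 genes; 2407 of them had over 1 such probe set. Passing probe sets with several symbols or none (3031) entered no named comparison. Values were transformed as log2(signal + 16) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) with 1 mean per group over all 12 arrays. This shares 1 estimate of the spread, with 8 residual and 5.84 prior degrees of freedom; the median residual SD was 0.178 in Sprague-Dawley and 0.150 in Han Wistar livers. Contrasts were germ-free minus conventional, antibiotic minus untreated control, and the difference between them. Strain was never compared directly. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.144.

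Before the data were examined, 26 gene lists were fixed, covering bile acid, lipid, glucose, sulphur amino acid and xenobiotic metabolism, inflammation, interferon, MHC class II, clock, cell cycle, stress, growth hormone and liver zonation genes, and markers of 7 other cell types. Each list with at least 3 tested members was tested with camera (correlation 0.01), with camera and an estimated correlation, and with fry, adjusted over the 26 lists. In germ-free livers camera called 9 lists, the estimated correlation 0 and fry 10. For the difference between the comparisons these were 7, 0 and 7. Every list that camera called in germ-free livers also passed fry, other than the growth hormone list (fry adjusted p = 0.0804). Some list genes were not analysed here, and counts are of the members tested.

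The rule for named genes, also fixed then, took per comparison the 10 genes with the highest and the 10 with the lowest log2 fold change among those that passed and whose groups did not overlap. Where fewer than 10 passed in all, genes with the smallest p were added up to 10. The rule always took Cyp7a1, Cyp8b1, Cyp27a1, Cyp7b1, Baat, Slc27a5, Nr0b2, Nr1h4, Abcb11 and Slc10a1 where tested, and up to 4 members of each list by smallest p. For the difference it took the 5 highest and 5 lowest genes. Other members of lists and the genes in the closing observations were chosen after their values were seen.

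The fit was tested on simulated data with 200 of 9300 genes changed. For the germ-free comparison it recovered 29.9% of genes changed by 0.5, 83.6% by 1 and 98.5% by 2 on the log2 scale, with 5 false calls. For the antibiotic comparison these shares were 29.9%, 86.6% and 100%, with 11 false calls, and data with no simulated change gave 0. The simulated noise was normal and independent between genes, with 1 SD per gene. These shares hold for 200 changed genes. With few genes called, as in the real antibiotic comparison (2), the adjusted threshold is stricter, so they do not give its power. RNA quality was checked by the 3' to 5' signal ratios of the actin and Gapdh controls, with exact permutation tests. Alternatives tried were offsets of 1 and 64, no filter and a 75th percentile filter, quantile normalization, median centring, fits on each comparison's own 6 arrays, no variance trend, a robust prior, array weights, the mean of a gene's probe sets, every probe set, and leaving out each animal. The actin ratio as a covariate and the removal of RT1 genes were added after seeing the data. Figures were drawn with matplotlib 3.10.9.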

Results

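Gene expression was measured in rat liver with 1-colour Affymetrix arrays, 1 array per animal and 12 arrays in all. Livers of 3 germ-free Sprague-Dawley rats, animals reared without microbes, were set against those of 3 conventional Sprague-Dawley rats. Livers of 3 Han Wistar rats given streptomycin and penicillin in the drinking water for 8 days were set against those of 3 untreated Han Wistar rats. Together the comparisons ask how liver transcripts differ in rats without microbes and in rats given antibiotics. For the germ-free and conventional groups the labels give no time of tissue collection, diet or age. A difference in any of these cannot be told apart from germ-free state in the results below. The arrays of a group correlated at 0.977 to 0.987 across genes, and no arrays held identical values. The first principal component (35.3% of the variance) separated the strains, which were also the separate experiments, and the second (22.8%) separated germ-free from conventional livers. Each limma p-value below sets a difference against the spread between animals within groups, pooled over all 12 arrays. The number of animals limits the precision. Camera p-values set the genes of a list against the other genes, with a preset correlation of 0.01. Fold changes are on the log2(signal + 16) scale and understate the change of dim genes.

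In germ-free livers, genes of cholesterol synthesis fell together. Of 19 members tested, 14 fell, 0 rose and 5 did not pass (median log2 fold change -0.97), and 17 fell when adjusted over the list alone. Sqle, the squalene epoxidase, changed by -3.01 ± 0.27 (log2 ± SE), Idi1 by -2.64 ± 0.23, Cyp51 by -2.41 ± 0.17 and Msmo1 by -2.31 ± 0.27 (3 against 3 animals). The signal of Cyp51, a demethylase of the same pathway, was 520.4 ± 96.3 (SD) in germ-free and 2805 ± 175 in conventional livers. Genes of fatty acid oxidation, many of them targets of the nuclear receptor PPAR-alpha, fell as well. Of 23 tested, 14 fell, 0 rose and 9 did not pass (median -0.72), and 15 fell and 1 rose when adjusted over the list alone. Acot1, an acyl-CoA thioesterase, changed by -3.36 ± 0.55, Vnn1 by -3.13 ± 0.38, the peroxisomal gene Pex11a by -1.96 ± 0.26 and Ehhadh, an enzyme of peroxisomal oxidation, by -1.45 ± 0.24. Both lists passed camera (adjusted p = 5.8e-17 and 1.3e-10) but not with an estimated correlation (adjusted p = 0.196 with an estimated correlation, for each). Both also passed fry (adjusted p = 0.00143 and 0.00292). In antibiotic-treated livers 0 members of either list passed limma's test, with 969 genes of all 9300 at an unadjusted p under 0.05.

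**Figure D1:**
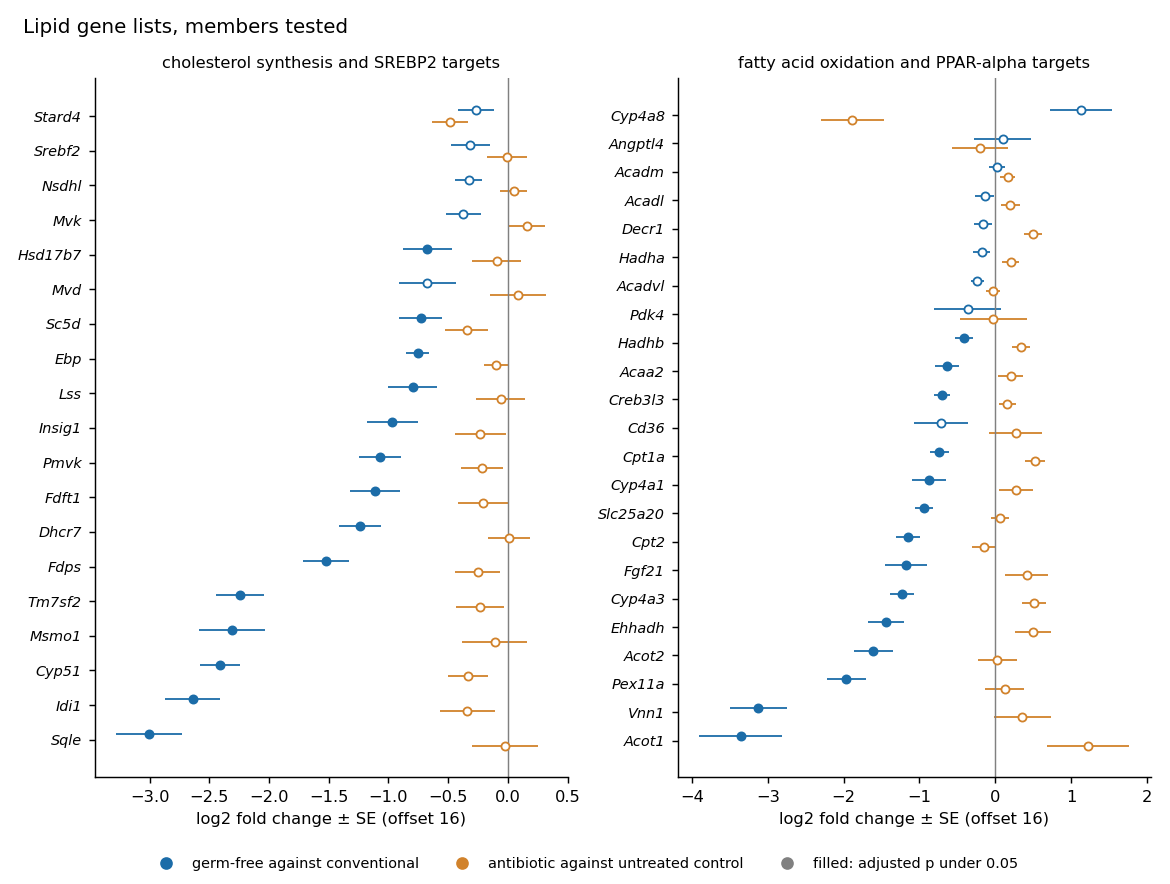
Log2 fold change with its standard error (x axis, offset 16) of each tested member of the cholesterol synthesis list (left) and the fatty acid oxidation list (right), in blue for germ-free against conventional and in orange for antibiotic against untreated control livers, 3 animals per group. Filled points passed an adjusted p of 0.05, which 14 members of each list did in germ-free livers and 0 in antibiotic-treated livers.

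Across all genes, 1226 of 9300 differed between germ-free and conventional livers by limma at an adjusted p under 0.05, 599 higher and 627 lower, and 229 of these changed over 2-fold (105 higher, 124 lower). The groups did not overlap for 2782 genes (29.9%, where chance gives 10%). Without germ-free animal 3 the count was 654. RNA quality was read from the 3' to 5' signal ratio of beta-actin, which rises as RNA degrades: 4.39 ± 0.762 in germ-free and 5.37 ± 0.839 in conventional livers (SD, n = 3; exact permutation test, two-sided p = 0.2, where the smallest possible p is 0.1). With that ratio as a covariate, an alternative added after seeing the data, 606 genes passed.

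The genes with the highest changes were led by Stac3, with a signal of 1924 ± 401 in germ-free and 38.1 ± 9.95 in conventional livers (log2 5.16 ± 0.36, adjusted p = 3.55e-06 by limma). Sds, the serine dehydratase that breaks down serine, followed with 3145 ± 320 against 185 ± 80.8 (log2 4.05 ± 0.47, adjusted p = 0.000125). Clca2 rose by 3.13, Hsd17b2, a steroid dehydrogenase, by 2.75, Elapor1 by 2.44, Srebf1 by 2.44, Nr1d1 by 2.39, Rtp4 by 2.36, Mtmr7 by 2.27 and Rtn4ip1 by 2.19. Among the lowest was Gsta3, a glutathione transferase, with 2.7 ± 1.82 against 376 ± 150 (log2 -4.32 ± 0.29). Its germ-free signal lay under the filter value of 19.67, and its log2 change was -6.69 with an offset of 1 and -2.66 with 64, so its size and rank depend on the offset. The same holds for other named genes with 1 group under that value: Fam111a (-5.29 and -2.29), Phgdh (-4.53 and -1.49), RT1-A (-3.58 and -1.60), Acot1 (-5.14 and -2.09), Sqle (-3.88 and -1.94), Clca2 (3.99 and 2.02) and Elapor1 (3.31 and 1.43). Fam111a changed by -3.71, the MHC class I gene RT1-CE12 by -3.60, Cavin3 by -3.15, the acetyltransferase gene Nat8 by -2.98 and Phgdh, the entry enzyme of serine synthesis, by -2.74. RT1-A changed by -2.65 (adjusted p = 0.0216), a call that was lost without germ-free animal 1 (0.0581), 3 (0.0524) or 4 (0.0574) or conventional animal 7 (0.0744). A robust prior or the actin covariate ended it as well. Gsta3, Acot1 and the RT1 genes belong to families of near-identical copies, so a probe set may read more than 1 of them.

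Among the genes of bile acid handling, Cyp7a1 rose and several transporters fell. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a signal of 1292 ± 426 in germ-free and 355 ± 90.2 in conventional livers (log2 1.79 ± 0.53, adjusted p = 0.0386). This call was lost without germ-free animal 1 (adjusted p = 0.0936) or 3 (0.134) and without conventional animal 6 (0.0561), 7 (0.079) or 8 (0.113), and also with no filter (0.0639), a robust prior (0.113) or the actin covariate (0.147; log2 1.76). Of the 15 tested genes of synthesis and conjugation 2 rose, 2 fell and 11 did not pass (3 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.941). Cyp8b1, the 12-alpha-hydroxylase, had a log2 change of 0.56 ± 0.18 (adjusted p = 0.0567), Cyp27a1 of -0.20, Baat of 0.12 and Slc27a5 of -0.34, and Cyp7b1 lay under the signal filter. Cyp8b1 passed without conventional animal 6 (0.0219), and Cyp27a1 (0.0396) and Slc27a5 (0.00393) passed without germ-free animal 1. Of 13 transporters 6 fell, 1 rose and 6 did not pass, with the same counts adjusted over the list alone (median -0.12; camera adjusted p = 0.0102, and adjusted p = 0.196 with an estimated correlation). The canalicular sterol transporters Abcg5 (-2.10 ± 0.15) and Abcg8 (-1.85 ± 0.18; -2.56 with an offset of 1 and -1.04 with 64) and the phospholipid transporter Abcb4 (-1.37 ± 0.13) fell most. With the filter raised to the 75th percentile of signals, which tests fewer genes, this list no longer passed (adjusted p = 0.269). Abcb11, the bile salt export pump, changed by -0.59 ± 0.16 (adjusted p = 0.0254), a call lost without germ-free animal 4 (0.104) or conventional animal 7 (0.0798) or 8 (0.0696) or with the actin covariate (0.167; log2 -0.50), and Slc10a1, the uptake carrier, had a log2 value of 0.00. Of 12 sensing receptors 2 rose, 1 fell and 9 did not pass (5 and 1 adjusted over the list alone). Nr1i3, the xenobiotic receptor CAR, changed by -1.55 ± 0.26, while Nr0b2 had a log2 value of 1.27 (adjusted p = 0.0828, and 0.0156 without conventional animal 7) and Nr1h4, the bile acid receptor FXR, of 0.28 (adjusted p = 0.234). That list passed camera at an adjusted p of 0.0464 (adjusted p = 0.196 with an estimated correlation), but not without germ-free animal 3 (0.0625) or 4 (0.118), conventional animal 6 (0.0583) or untreated control animal 1 (0.0512), nor under the 75th percentile filter (0.0645), no variance trend (0.0547) or the actin covariate (0.0576).

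**Figure D2:**
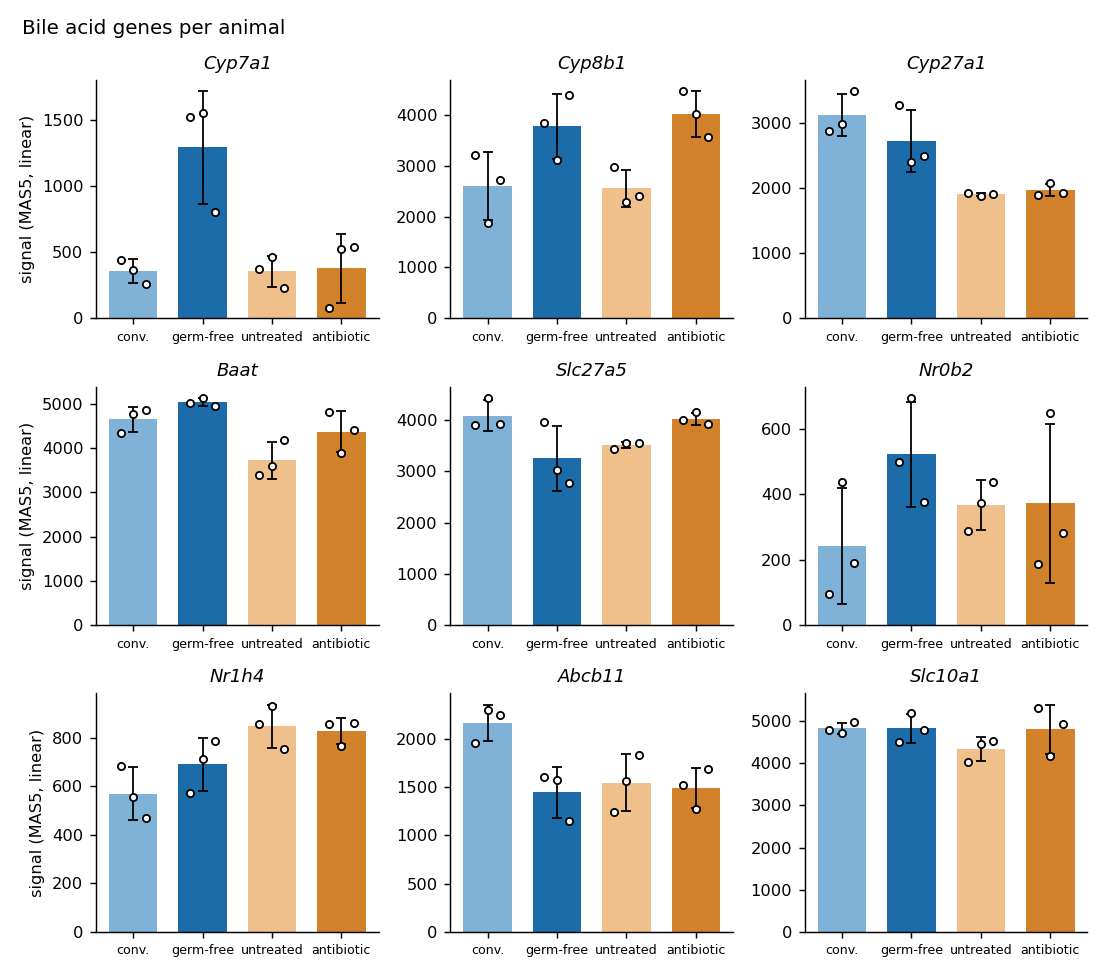
Signal (y axis, linear MAS5 units) of 9 bile acid genes in conventional, germ-free, untreated control and antibiotic-treated livers, with bars at the mean, error bars of 1 SD and a point for each of 3 animals. Cyp7a1 averaged 1292 in germ-free against 355 in conventional livers, and 379.7 in antibiotic-treated against 356 in untreated livers.

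Fatty acid synthesis genes went both ways: of 18 tested, 3 rose, 6 fell and 9 did not pass (6 and 6 adjusted over the list alone; camera adjusted p = 0.352). Srebf1, a transcription factor of lipid synthesis, rose by 2.44 ± 0.39 and Thrsp by 2.09 ± 0.49, while the desaturase gene Fads2 changed by -1.90 ± 0.20 and malic enzyme, Me1, by -2.14 ± 0.24. Thrsp lost its call without germ-free animal 3 (0.0674), with a robust prior and with the actin covariate. In glucose metabolism, 3 of 17 genes rose, 0 fell and 14 did not pass (4 rose and 1 fell adjusted over the list alone; median 0.32; camera adjusted p = 0.0402, and adjusted p = 0.203 with an estimated correlation). Those that rose were Sds, Tat, the tyrosine aminotransferase (1.74 ± 0.14), and the glycogen phosphorylase gene Pygl, so that the first pair are enzymes of amino acid breakdown. The Pygl call, a log2 change of 0.60, was lost without germ-free animal 3 (0.0778) or 4 (0.064) or conventional animal 6 (0.0647). The list did not pass without germ-free animal 3 (0.0625) or conventional animal 6 (0.0892) or 7 (0.0749), with no variance trend (0.0547) or with the mean of probe sets (0.0602). Of 11 genes typical of periportal hepatocytes 3 rose, 0 fell and 8 did not pass (7 rose adjusted over the list alone; median 0.40, mean 0.78; camera adjusted p = 0.000151, and adjusted p = 0.196 with an estimated correlation). Among those that rose were Hal, the histidine ammonia-lyase (1.23 ± 0.20), and again Sds (4.05). Sds and Pck1 belong to both the glucose and the periportal list, so these list results are not independent. Of 9 pericentral genes 1 fell, Lect2 (-0.70 ± 0.12), and 8 did not pass (2 higher and 2 lower adjusted over the list alone; adjusted p = 0.941). In sulphur amino acid and one-carbon metabolism 3 of 16 rose, 2 fell and 11 did not pass (4 and 2 adjusted over the list alone; adjusted p = 0.0881). Gldc, of the glycine cleavage system, rose by 1.27 ± 0.20 and Csad, of taurine synthesis, changed by -1.15 ± 0.15. That list passed without germ-free animal 1 (0.0484) or conventional animal 8 (0.00808).

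Interferon-stimulated genes were higher in germ-free livers. Of 24 tested, 13 rose, 0 fell and 11 did not pass, and 16 rose adjusted over the list alone (median 0.66; camera adjusted p = 3.56e-08, and adjusted p = 0.196 with an estimated correlation). Usp18, which restrains interferon signalling, rose by 2.10 ± 0.26 (signal 244 ± 43.2 against 46.3 ± 19.4), Isg15, a ubiquitin-like protein, by 1.74 ± 0.20, the transcription factor Irf7 by 1.28 ± 0.19 and Mx1 by 1.07 ± 0.19 (1.65 with an offset of 1 and 0.52 with 64). Depending on the alternative, the median of the interferon list lay between 0.33 and 0.85. Acute phase genes did not pass as a list (adjusted p = 0.352): of 25, 1 rose, 1 fell and 23 did not pass (0 and 1 adjusted over the list alone). Cd14, the co-receptor for bacterial lipopolysaccharide, fell from 1084 ± 237 to 446 ± 171 (log2 -1.31 ± 0.24, adjusted p = 0.00275). Of 8 genes of MHC class II presentation 1 rose, 0 fell and 7 did not pass (2 rose adjusted over the list alone; adjusted p = 0.113, and 0.0141 without conventional animal 7). The gene that rose, RT1-Bb, had a log2 change of 2.05 (adjusted p = 0.019) from its brightest probe set and of -2.31 from its other one, -0.13 as their mean, and lost its call without germ-free animal 3 (0.0672) or conventional animal 7 (0.0783), so its direction is not settled.

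**Figure D3:**
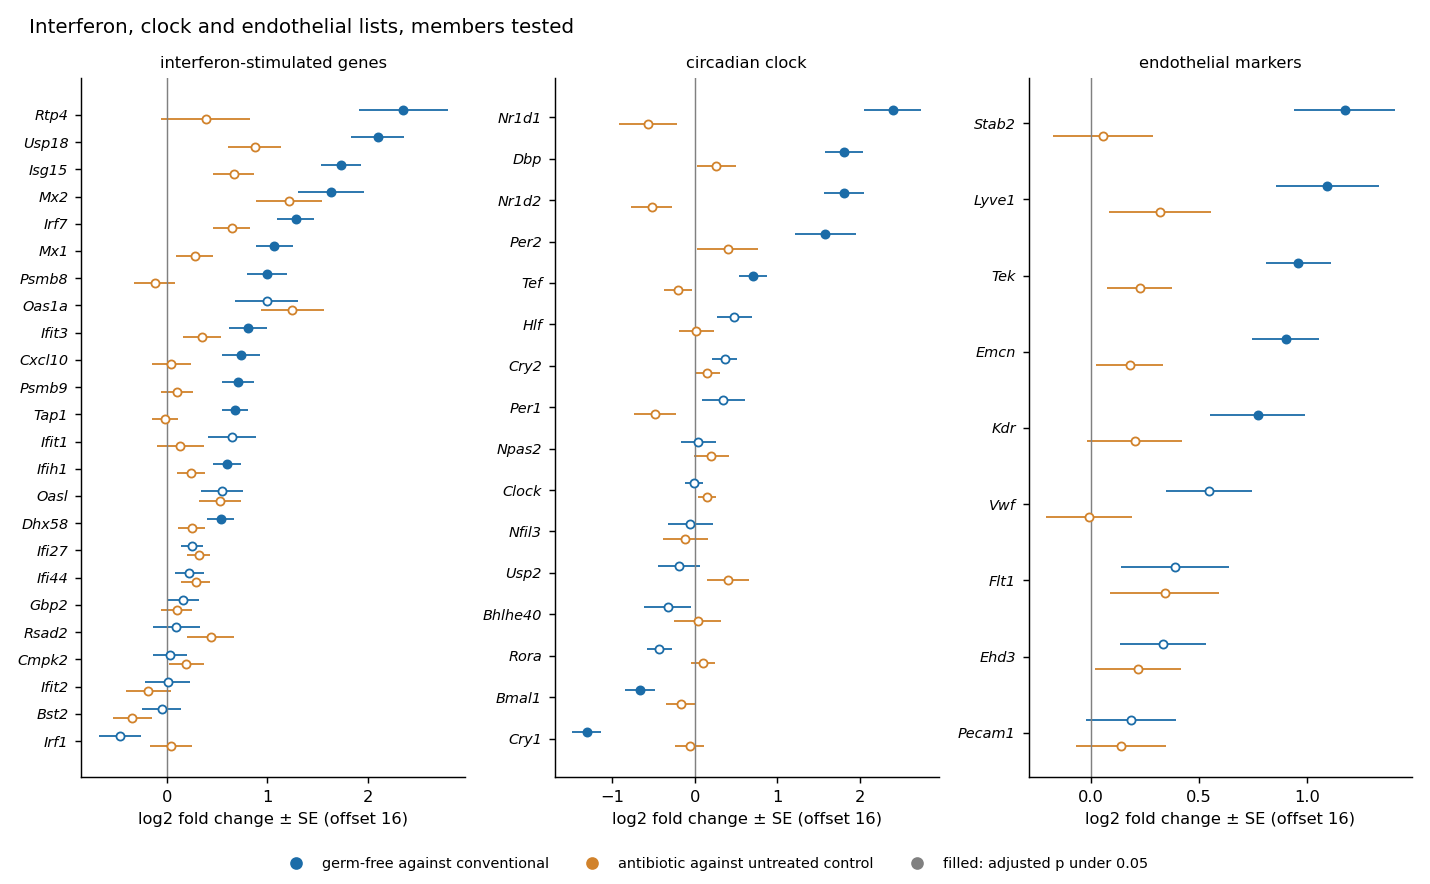
Log2 fold change with its standard error (x axis, offset 16) of each tested member of the interferon, circadian clock and endothelial lists, in blue for germ-free against conventional and in orange for antibiotic against untreated control livers, 3 animals per group. Filled points passed an adjusted p of 0.05: 13 interferon, 7 clock and 5 endothelial genes in germ-free livers, and 0 in antibiotic-treated livers.

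Genes of xenobiotic metabolism changed in both directions. In phase I oxidation 2 of 23 rose, 5 fell and 16 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.511). Aldh1a1, a retinal dehydrogenase, changed by -2.61 ± 0.31 (signal 348 ± 109 against 2150 ± 341) and Fmo5 by -1.67 ± 0.32, while Cyp3a9 rose by 1.19 ± 0.27. In phase II conjugation 4 of 31 rose, 7 fell and 20 did not pass (5 and 7 adjusted over the list alone; camera adjusted p = 0.25, fry adjusted p = 0.00364, mean log2 -0.32), with Gsta3 and Nat8 lowest and Gstm7 (0.84 ± 0.13) highest. Of 20 stress genes 2 rose, 5 fell and 13 did not pass (3 and 5 adjusted over the list alone; adjusted p = 0.0881), a list that passed without conventional animal 7 (0.0421) or 8 (0.0274). Asparagine synthetase, Asns, changed by -2.46 ± 0.32 (-3.36 with an offset of 1 and -1.46 with 64, as its germ-free signal of 13.3 lay under the filter value), Srxn1, an oxidative stress gene, by -1.81 ± 0.24 (-0.65 from its other probe set, adjusted p = 0.171) and Sesn2 by 1.81 ± 0.14. Of 6 cell cycle genes 1 fell, Ccnd1 (cyclin D1, -1.41 ± 0.22), and 5 did not pass, also adjusted over the list alone (adjusted p = 0.485). Most members of that list lay under the signal filter, and with no filter, where 25 were tested, it passed (median -0.26, adjusted p = 3.52e-05).

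Core clock genes moved in opposite directions. Of 16 tested, 5 rose, 2 fell and 9 did not pass (5 and 3 adjusted over the list alone), and the list, whose members go both ways, did not pass camera (adjusted p = 0.209, and 0.0412 with no filter) but did pass fry (adjusted p = 0.00377). The repressors Nr1d1 (2.39 ± 0.35) and Nr1d2 (1.80 ± 0.24) and the output factor Dbp (1.81 ± 0.23) rose, and Cry1 changed by -1.31 ± 0.17. Per2 rose by 1.58 and Tef by 0.71, calls that were lost without germ-free animal 3 (0.0633 and 0.0544), and Bmal1 changed by -0.66, a call lost without germ-free animal 1 (0.0871) or 3 (0.111) or conventional animal 6 (0.0622) or 8 (0.0812). Times of tissue collection are not given in the labels. Of 16 growth hormone responsive genes 3 rose, 1 fell and 12 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.0491, and adjusted p = 0.553 with an estimated correlation). Igfals, the carrier subunit of circulating IGF, rose by 1.20 ± 0.18, Hao2 by 0.83 and Bcl6 by 2.07. Cish changed by -1.73 (adjusted p = 0.0431 by limma), a call lost in 14 of 24 alternatives. The list does not separate genes that growth hormone raises from those it lowers, so its direction gives none for growth hormone signalling. The list's p stood just under the threshold and rose above it in 17 of 26 alternatives. Among these were the fits without germ-free animal 3 (0.0804) or 4 (0.118), conventional animal 6 (0.137) or 7 (0.0749), untreated control animal 1 (0.0669), 2 (0.0523) or 3 (0.0508) or antibiotic animal 15 (0.0617).

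Markers of other cell types moved unequally. Of 9 endothelial markers 5 rose, 0 fell and 4 did not pass (6 rose adjusted over the list alone; median 0.77; camera adjusted p = 0.000129, and adjusted p = 0.203 with an estimated correlation), with Stab2 at 1.17 ± 0.23, Tek at 0.96 ± 0.15 and Emcn at 0.90 ± 0.15. Of 10 macrophage markers 1 fell and 9 did not pass (2 fell adjusted over the list alone; adjusted p = 0.25). The one that fell, the Kupffer cell lectin Clec4f (-0.64), lost its call without germ-free animal 1 (0.069) or 4 (0.0897) or conventional animal 7 (0.107) or 8 (0.0503). Among the endothelial markers Kdr (0.77) lost its call without germ-free animal 1 (0.0936) or 3 (0.125) or conventional animal 6 (0.1), 7 (0.0641) or 8 (0.0569). Emcn ran from 0.49 to 1.22 over the alternatives, and the median of the endothelial list from 0.49 to 1.025. Lymphocyte (5 tested, adjusted p = 0.643), bile duct (3, 0.407) and stellate cell markers (12, 0.885) had 0 members that passed, over all genes or adjusted over the list alone. Of 5 erythroid markers 1 fell (Slc4a1, -0.69, lost without germ-free animal 1 (0.0536), 3 (0.122) or 4 (0.0516) or conventional animal 6 (0.11) or 7 (0.0546); list adjusted p = 0.941). Of 3 adipocyte and exocrine pancreas markers 0 passed (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.941).

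In antibiotic-treated livers, 2 of 9300 genes differed from untreated control by limma, both lower, and 969 had an unadjusted p under 0.05. Tmem14a had a signal of 8.67 ± 10.9 in antibiotic-treated and 87.2 ± 6.82 in untreated livers (log2 -2.15 ± 0.26, adjusted p = 0.00894), and Rusc2 of 32.7 ± 4.95 against 79.0 ± 6.41 (-0.97 ± 0.14, adjusted p = 0.0266). Neither gene passed without untreated control animal 2 (adjusted p = 0.0821 and 0.0907), and Tmem14a did not pass with an offset of 1 (0.11). The signal of Tmem14a in antibiotic-treated livers lay under the filter value. Its log2 change ran from -3.80 to -1.07 over the alternatives, so its size depends on the processing. Rusc2 also lost its call on the own 6 arrays (0.0839) and without untreated control animal 1 (0.0674) or 3 (0.0986), antibiotic animal 13 (0.0533) or 14 (0.143) or germ-free animal 3 (0.0556). Leaving out 1 animal gave 0 genes (untreated control animal 2), 1 (germ-free animal 3), 4 (antibiotic animal 15 or conventional animal 7), 5 (untreated control animal 1), 6 (conventional animal 6) or 10 (germ-free animal 1), and 2 or 3 otherwise. The groups did not overlap for 1703 genes (18.3%, where chance gives 10%). The actin ratio was 2.73 ± 0.131 in antibiotic-treated and 2.55 ± 0.123 in untreated livers (exact permutation test, two-sided p = 0.2). The genes next in order of p did not pass: Egfr, the epidermal growth factor receptor, had a log2 change of -0.95 and the sterol transporter gene Abcg5 of 0.92 (adjusted p = 0.053 for both), Ptgis of 1.17, Bco1 of 1.05, and Igfbp2, which binds insulin-like growth factors, of 3.03 ± 0.52 (468 ± 268 against 38.6 ± 13.2, adjusted p = 0.0633). Apoa2 followed with a log2 change of 0.50, Ctsl with 0.47 and Acbd6 with 0.68. Without germ-free animal 1 all of these but Ctsl passed (Egfr 0.0375, Ptgis 0.0433, Abcg5 0.0468, Bco1 0.0468, Igfbp2 0.0201, Apoa2 0.0468, Acbd6 0.0375). Egfr and Igfbp2 also passed without conventional animal 6 (0.0349 and 0.0472), Abcg5 without conventional animal 7 (0.0407) or 8 (0.0378), Ptgis without untreated control animal 1 (0.0106), Bco1 without antibiotic animal 13 (0.00843) and Egfr without antibiotic animal 14 (0.0416). Among the bile acid genes Cyp7a1 had a log2 value of -0.24 ± 0.53 (adjusted p = 0.933), whose sign follows antibiotic animal 13 (signal 78.3, against 523.3 and 537.5 in the others; log2 0.61 without it). Cyp8b1 had a log2 value of 0.65 ± 0.18 (adjusted p = 0.199) and Abcb11 of -0.04 ± 0.16 (adjusted p = 0.963).

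As sets, 10 of the 26 lists passed camera in antibiotic-treated livers, 9 higher and 1 lower, with 0 members passing individually over all genes. The estimated correlation left 0 lists (lowest adjusted p = 0.408 with an estimated correlation), and fry, which asks whether a set's genes move on balance one way, called 0 (lowest adjusted p = 0.0616). Macrophage markers had a median of 0.50 (adjusted p = 6.61e-05; 3 of 10 higher adjusted over the list alone), with the complement gene C1qa at 0.68 ± 0.17 and Cd68 at 0.63 ± 0.20. Interferon-stimulated genes had a median of 0.26 (adjusted p = 8.63e-05; 5 of 24 higher adjusted over the list alone), with Oas1a at 1.25 ± 0.31. After quantile normalization these 2 lists passed and the other 8 did not. Those 8 were phase I oxidation (median 0.30; 9 higher and 1 lower adjusted over the list alone), acute phase (0.22; 6 higher), periportal (0.35; 5 higher), fatty acid oxidation (0.20; 3 higher, 1 lower), bile acid synthesis (0.18; 2 higher), sulphur amino acid (0.18; 4 higher, 2 lower), stellate cell (0.17; 0) and cholesterol genes (-0.11; 0). The tenth of genes with the highest signal shifted by 0.0863 as a median, against 0.00154 for all genes. The interferon list did not pass under the 75th percentile filter (0.0547). Leaving out 1 animal ended the call of the fatty acid oxidation list (antibiotic animal 13, 0.0794) and of the cholesterol list (untreated control animal 2, 0.882; antibiotic animal 14, 0.677; conventional animal 6, 0.0507). It also ended that of the sulphur amino acid list (untreated control animal 1, 0.219, or 2, 0.0645; antibiotic animal 13, 0.148, or 14, 0.0534). The stellate cell list was lost without untreated control animal 2 (0.225), antibiotic animal 13 (0.11) or 14 (0.166), germ-free animal 1 (0.0583) or conventional animal 6 (0.0544) or 8 (0.0524).

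**Figure D4:**
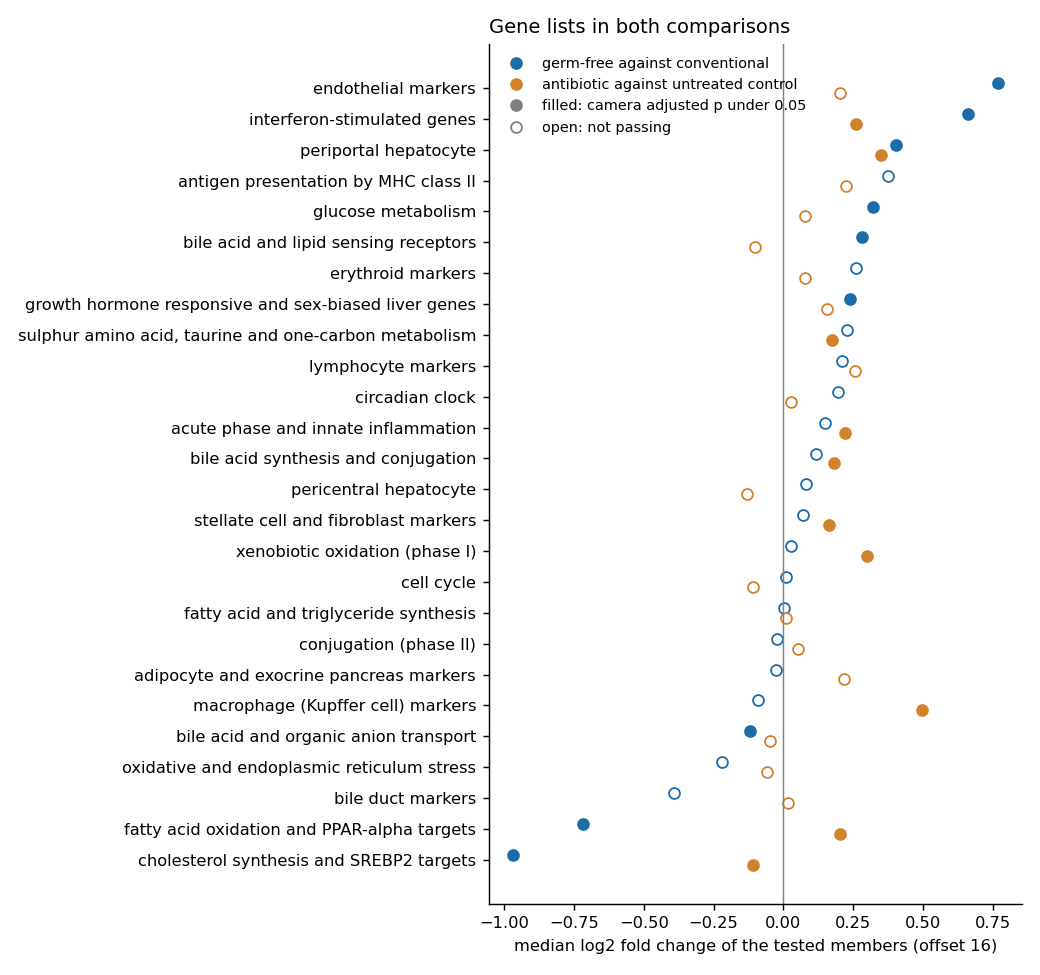
Median log2 fold change of the tested members (x axis, offset 16) of each of the 26 gene lists (y axis), in blue for germ-free against conventional and in orange for antibiotic against untreated control livers, 3 animals per group; filled points passed camera at an adjusted p of 0.05. The cholesterol list lay at -0.97 in germ-free and -0.11 in antibiotic-treated livers, and the macrophage list at -0.09 and 0.50.

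The germ-free and antibiotic changes were not correlated across genes (Pearson r = -0.0447, Spearman rho = 0.00352 over 9300 genes, which are not independent replicates). With 2 antibiotic genes called, error in the antibiotic values may hide a shared response here. Among lists that camera passed in both comparisons, interferon genes went the same way (22 and 20 of 24 positive). So did periportal genes (10 and 9 of 11 positive) and cholesterol genes (19 and 15 of 19 negative). Fatty acid oxidation genes went opposite ways (20 of 23 negative, then 18 of 23 positive). With an estimated correlation these lists passed in neither comparison. In antibiotic-treated livers only the interferon list among them still passed camera after quantile normalization, and fry called 0 lists there. The shared or opposite directions of the others therefore rest on calls that depend on the processing. Of the 1226 genes called in germ-free livers, 616 had the same sign in antibiotic-treated livers. The 1 gene called in both, Rusc2, had log2 changes of 0.97 and -0.97. The test of the difference between the changes called 552 genes, 250 with a higher change in germ-free livers and 302 with a lower one, and 296 without germ-free animal 3 or 313 without untreated control animal 2. Strain and experiment differ together with the kind of treatment here. RNA quality differs with them too. The actin ratio was 3.62 to 6.17 in Sprague-Dawley and 2.47 to 2.87 in Han Wistar arrays, so it also goes with the first principal component. Stac3 differed by 5.93 ± 0.51 and Bcl6, a repressor in growth hormone signalling, by 4.45 ± 0.74, with changes of 2.07 in germ-free and -2.38 in antibiotic-treated livers, of which the second did not pass (adjusted p = 0.173). The first was lost without germ-free animal 3 (0.0813) or 4 (0.055) or conventional animal 6 (0.052), and the second passed without conventional animal 6 (0.0472) or 7 (0.0407). Among lists, fatty acid oxidation (median difference -0.98, 15 of 23 genes lower and 1 higher) and cholesterol synthesis (-0.76, 8 of 19 lower) differed by camera (adjusted p = 2.04e-12 and 2.94e-12), though not with an estimated correlation (adjusted p = 0.274 with an estimated correlation, for each). Adjusted over the list alone, 16 and 14 were lower.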

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

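The tests on clock genes, endothelial markers, colony genotype and genes with a single probe set were chosen after the results were seen; those on genes with another probe set and on other splits of the arrays were written before. The test of the actin covariate was changed more than once after its results were seen: rules on how many single calls it kept (4 of 5, then every one, then by genes that kept them) gave way to fry on all tested members of each list.

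A total of 552 genes changed differently in germ-free than in antibiotic-treated livers by the test of the difference itself (296 without germ-free animal 3 and 313 without untreated control animal 2). The difference of the log2 changes was 5.93 for Stac3, 4.64 for Clca2, 4.45 for Bcl6, 3.56 for Sds and 3.25 for Hsd17b2. It was -4.64 for RT1-CE12, -4.59 for Acot1, -4.51 for Igfbp2, -4.07 for Gsta3 and -3.97 for RT1-N2, whose call was lost in 13 alternatives. Among these were the fits without germ-free animal 1 (0.0594), 3 (0.0809) or 4 (0.0661), conventional animal 6 (0.0557), 7 (0.0813) or 8 (0.0509) or antibiotic animal 13 (0.0829) or 14 (0.072). The lists that differed by camera had median differences of -0.15 (bile acid transport), -0.76 (cholesterol synthesis), -0.98 (fatty acid oxidation), -0.31 (phase I oxidation), 0.39 (interferon), -0.61 (macrophage markers) and 0.57 (endothelial markers). The bile acid transport list did not pass without conventional animal 8 (adjusted p = 0.0667) or antibiotic animal 13 (0.052), under the 75th percentile filter (0.264) or after quantile normalization (0.0971). The phase I list did not pass after quantile normalization (0.169) or with the actin covariate (0.0513), nor the endothelial list with the actin covariate (0.0539), and no list passed with an estimated correlation (lowest adjusted p = 0.274 with an estimated correlation). Among probe sets with several gene symbols or none, which the comparisons of named genes do not use, 368 of 3031 differed between germ-free and conventional livers (234 higher, 134 lower), and 1 between antibiotic-treated and untreated livers.

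Other splits of the same arrays gave fewer genes. For germ-free against conventional livers the real split gave 1226 genes and the highest of the other 9 splits 1, and for antibiotic against untreated livers 2 and 1. In each, 1 of 10 splits was as large as the real one, the real one itself, and 10 splits are too few for a share under 0.05. For the difference between the changes, 1 of 100 drawn joint splits, the real one, reached 552. The highest other gave 347 and, like the 7 further draws with over 1 gene, kept the real germ-free split. A draw that breaks this split adds the germ-free change to the spread shared by all groups, which by itself lowers the count. Draws that kept it but broke the antibiotic split gave 254 to 347 genes, also under 552. The draws therefore cannot show which comparison the count rests on. Of the 9 draws that keep the real germ-free split 1, the real one, was as large, and 9 are too few for a share under 0.05.

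Clock genes changed in germ-free livers, with Nr1d1, Nr1d2, Dbp, Per2 and Tef higher and Cry1 and Bmal1 lower. A candidate explanation is a different time of day at tissue collection. The median log2 change was 1.58 for 7 genes of one phase and -0.05 for 5 genes of the opposite phase, medians that differ by 1.63. Clock, Npas2 and Nfil3 of the second set and Hlf (0.48) and Per1 (0.35) of the first did not pass. The labels give no times, so time of day and group cannot be told apart. With the actin ratio as a covariate the list of 16 still passed fry (adjusted p = 0.0281, and 0.00377 without it). The rule for this covariate was changed after its results were seen, so it does not settle the part of RNA integrity. Of the 7 called genes 4 stayed past the threshold, and the calls ended for Per2 (1.58 ± 0.37 before, 0.97 ± 0.36 with it) through a smaller change and, mainly through a larger error, for Tef (0.71 ± 0.17, 0.65 ± 0.21) and Bmal1 (-0.66 ± 0.18, -0.73 ± 0.23), all 3 of which were also lost without germ-free animal 3 (0.0633, 0.0544 and 0.111). A part played by RNA integrity and an effect of the missing microbiota itself stay open.

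Changes over 2-fold (229 genes) included near on or off differences such as Gsta3 and Fam111a, which have no other passing probe set. A sequence difference under the probes of a single probe set would leave a gene's other probe sets in place. Yet 58 of 78 other probe sets, from 56 genes, moved the same way by at least 0.5 times as much (74.4%, exact 95% interval 63.2 to 83.6%). This argues against a sequence difference as the general cause in these genes. The interval takes the probe sets as independent, though some genes have several, so it is too narrow. The other 173 genes, Stac3, Sds, RT1-CE12 and Acot1 among them, have no other passing probe set, so there it cannot be told apart from a change in level. Another genotype in the germ-free colony may also account for part: 6 of 15 RT1 genes were called (40%, against 13.2% of all genes), 2 higher and 4 lower, where 1 of the 2 is RT1-Bb with -2.31 from its other probe set and -0.13 as their mean. This share decides nothing, since RT1 genes were looked at after RT1-CE12 and RT1-A had been seen to change and their copies are not independent. Genotype was not measured and would go with the germ-free group, so it and germ-free state cannot be told apart here, and the calls of RT1-A, RT1-N2, RT1-T24-4 and RT1-Bb were lost in several alternatives, among them the one without germ-free animal 3 (0.0524, 0.0865, 0.0533 and 0.0672).

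Endothelial markers were higher in germ-free livers (mean log2 change 0.70 over 9 markers). A lower share of hepatocytes would raise all other cell types alike, but 30 macrophage, lymphocyte, stellate cell and bile duct markers had a mean of -0.03. The difference was 0.74 with a standard error of 0.0882 between animals. Per array, the endothelial mean minus the other was 0.10 to 0.29 in germ-free and -0.65 to -0.42 in conventional livers, which argues against an equal rise of all these types. The lists were known to differ when this was chosen, and lymphocyte (5) and bile duct markers (3) were few. A lower share of hepatocytes together with changes in other cell types is not excluded. With the actin ratio as a covariate the endothelial list still passed fry (adjusted p = 0.0304, and 0.00371 without it). Camera lost that list with an estimated correlation (adjusted p = 0.203). As for the clock list, the rule for the covariate was changed after its results were seen, so it does not settle the part of RNA integrity. Of the 5 called markers 4 stayed past the threshold, and Kdr did not (0.77 ± 0.22 before, 0.83 ± 0.28 with it) because its error grew; it was also lost without germ-free animal 1 (0.0936) or 3 (0.125) or conventional animal 6 (0.1), 7 (0.0641) or 8 (0.0569). A part played by RNA integrity, a change in endothelial cells or their transcripts and an effect of the missing microbiota stay open.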

How the results depend on the processing

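The actin covariate and the removal of RT1 genes were chosen after seeing the data. The germ-free count of 1226 stayed between 849 and 1690 under all alternatives other than 1901 (1065 higher) with every probe set, where more features are tested, 606 (282 higher, 324 lower) with the actin covariate, and 654 without germ-free animal 3. Leaving out 1 animal gave 654 to 1236 genes (304 to 586 higher, 350 to 656 lower). The antibiotic count of 2 was 1 with an offset of 1 (1 lower), 4 with no filter (4 lower), 0 under the 75th percentile filter (0 lower), 6 with a robust prior (3 higher) and 15 with array weights (10 higher, 5 lower). Tmem14a and Rusc2 were not tested under the 75th percentile filter, so the 0 there shows no loss of their calls. In the antibiotic comparison 1 gene was higher with median centring, on the own 6 arrays and with every probe set. Leaving out 1 animal gave 0 to 10 (0 to 7 higher, 0 to 4 lower). The difference count of 552 was 869 with array weights (389 higher, 480 lower) and 230 with the actin covariate (106 and 124), 383 genes were higher with every probe set, and leaving out 1 animal gave 296 to 600 (122 to 257 higher, 172 to 343 lower). The correlation of the comparisons of -0.0447 was -0.0269 with no filter, -0.0664 under the 75th percentile filter, -0.0647 after quantile normalization, -0.0283 with array weights, -0.129 with the actin covariate and -0.0589 to -0.0139 with 1 animal left out. The lists called (9 in germ-free, 10 in antibiotic, 7 in the difference) were 0 in each with an estimated correlation and 2 in antibiotic-treated livers after quantile normalization; leaving out 1 animal gave 6 to 11, 7 to 11 and 7 to 8. The acute phase list in antibiotic-treated livers turned from 0.222 to -0.0414 after quantile normalization, and RT1-Bb in germ-free livers to -0.13 with the mean of probe sets, as its probe sets disagree. Where no cause is named, the cause was not tested. Over all alternatives, named genes stayed on the same side of the threshold 6443 times, lost a call 160 times, gained one 84 times and lost one with a turn of direction 1 time; for lists these were 1866, 93, 24 and 1. Turns of sign in results that did not pass are not counted among these. No paired analysis was possible because the groups of each comparison share no animal number. Signals near the filter value of 19.67 limit what dim genes can show.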

Other observations

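The genes here were chosen after their values were seen, apart from Phgdh, Asns and Sds, and no list of them was tested. Phgdh and Psat1, enzymes of serine synthesis, and the asparagine synthetase Asns were lower in germ-free than in conventional livers. Phgdh had a signal of 6.2 ± 4.99 against 144 ± 87.5 (SD, n = 3), Psat1 of 15.3 ± 5.69 against 126 ± 96.1 (log2 -2.00 ± 0.32, adjusted p = 0.00124 by limma; -2.77 with an offset of 1 and -1.16 with 64) and Asns of 13.3 ± 3.76 against 168 ± 125. Psph, the last enzyme of serine synthesis, had 75.6 ± 4.59 against 75.3 ± 18.3 and did not pass (log2 0.02, adjusted p = 0.943). Sds, which breaks serine down, was higher by 4.05. In the Han Wistar groups Phgdh had 10.5 ± 3.42 in untreated and 6.2 ± 2.21 in antibiotic-treated rats, Psat1 had 16.2 ± 2.56 and 11.8 ± 5.27, and Asns had 16.9 ± 6.33 and 13.6 ± 3.40. These Han Wistar values lie under the filter value of 19.67, where sizes depend on the offset.

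Other genes highest in conventional livers were the lipid droplet gene Plin5, with 22.9 ± 8.55 in germ-free, 93.0 ± 2.43 in conventional, 21.4 ± 1.68 in untreated and 25.7 ± 4.35 in antibiotic-treated livers, and Fkbp5, a glucocorticoid-responsive gene, with 87.2 ± 16.2, 204 ± 62.4, 86.6 ± 11.3 and 88.9 ± 7.67. Plin2, another lipid droplet gene, had 1371 ± 198, 3258 ± 439, 1743 ± 65.8 and 2185 ± 232 (log2 -1.24 in germ-free livers), but its other probe set had a log2 value of 0.22 (adjusted p = 0.448) and the mean of both -0.51. The heat shock gene Hspb1 was lowest in germ-free livers, with 42.5 ± 9.35 against 187 ± 88.9 in conventional, 234 ± 53.3 in untreated and 256 ± 88.8 in antibiotic-treated livers. Klf15, a regulator of amino acid breakdown, rose from 471 ± 125 to 1376 ± 73.8 (log2 1.55, adjusted p = 0.000301). Levels across strains were not tested, since strain and experiment differ together. On all 12 arrays the Y-linked gene Eif2s3y had a signal of 287.6 to 478.9, and the Xist probe sets stayed at or below 12.1.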
